A study of Homo sapiens with 4 samples.

How the data were processed

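Gene expression was measured in KMS12 and MM.1S, established human multiple myeloma cell lines, that had been cultured with hyaluronan either without shear stress (static) or under shear stress. Per the labels' protocols, the cells were kept for 24 hours in conditioned medium from bone marrow stromal cells, and total RNA was extracted with Trizol and labelled by T7 transcription. The RNA of the static culture carried the dye Cy3 and the RNA of the shear culture carried Cy5, and both were hybridised to the same array. The 4 samples therefore lay on 2 arrays, 1 per line, and each of the 4 groups held 1 sample. Both files of a line were identical and were read once. The dyes were not swapped, so that the dye and the condition cannot be told apart on a single array. Nothing in the labels describes a repeat culture. How shear stress was applied is not given in the sources used here.

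The deposited scanner files hold spot intensity values for both dyes on a linear scale, with local background signals and quality flags for each spot, per the file headers made with Agilent Feature Extraction 12.0.3.1. The deposited files also hold log10 ratios of red (Cy5) over green (Cy3) and an error of each ratio, computed by that software after its own background and dye corrections, per the file headers. The deposited value table of the series equalled the software's processed intensity signals at all 62969 spots it lists on each array, within a relative tolerance of 0.0001. Its columns had medians of 8.90 (KMS12 static), 8.24 (KMS12 shear), 8.55 (MM.1S static) and 8.12 (MM.1S shear), on a linear scale without centring. Its direction follows the dye labels. Of the columns with values per sample, 0 were left unused.

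Each array held 62976 spots, of which 60901 read genes, with 58201 different probes of 60 nucleotides. Control spots and spots with an outlier flag (153 on the KMS12 array and 146 on the MM.1S array) were left out of the gene values. No gene spot was saturated. Of the gene spots, 48.4% (KMS12) and 48.1% (MM.1S) were well above background in the static channel, and 43.6% and 43.2% in the shear channel. The number of arrays limits the precision of every value.

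For the main values, the background was corrected with normexp (offset 50) on the mean spot signal and the local background, and each array was normalized within itself by loess in limma 3.58.1 (R 4.3.3), with control and outlier spots given no weight. Spots of one probe were averaged. A gene with several probes was represented by the probe with the highest mean log2 intensity, and the text gives other probes for some of the named genes. A gene entered the comparison of a line only if its probe was well above background in both channels of that array. Probes were named by matching their accession to the RefSeq gene table (31104 probes), or else by symbol (3366) or by an older synonym (496). The remaining 23235 probes kept the name in the file. Of the 43403 distinct names, 22451 were gene symbols. Probe positions are those of the files, on the human build hg19.

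All ratios are log2 of shear over static. A normexp offset draws ratios towards 0, and this draw is larger for dim probes. Within a line there were no replicates, so its ratios carry no test. The technical spread was measured on 300 probes printed at 10 spots each. The median SD of their log2 ratios over spots was 0.051 in KMS12 and 0.052 in MM.1S. The error that the scanner software assigns to a ratio had a median of 0.21 on the log2 scale in both lines. Neither covers the spread between cultures.

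Over both lines, limma (lmFit and eBayes with an intensity trend) tested whether the mean of both ratios differed from 0, with 1 residual degree of freedom per gene and Benjamini-Hochberg adjustment at 0.05. This test takes each line as a replicate. It also counts a dye bias of a probe as a change, since the bias has the same sign on both arrays. Such bias cancels in the difference between the ratios of the lines only if it is equal on both arrays, and this difference has no replicate and no test. Levels of the lines were compared within each dye after quantile normalization between the arrays. A gene well above background in only 1 of the samples compared is given as a bound, against the higher of its own signal and the lowest signal among probes well above background. Bounds between conditions used loess and Aquantile values and are open to dye bias. No bound holds a margin for the error of the signals.

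For each of 31 gene lists, the median ratio per line was set against the medians of 10000 random lists of the same size, matched on mean intensity in 20 bins. The bins held equal numbers of genes, so the matching is coarse for the brightest genes. A median in a line is over the members measured in that line, so the medians of both lines can rest on different genes. The percentile describes these arrays and is not a test. The numbers of members past the limma threshold are given with the adjustment over all genes and as adjusted over the list alone. The genes named in the text followed a rule. It took the 8 highest and 8 lowest ratios in each line, and the 10 highest and 10 lowest over both lines by the smaller of the ratios. It also took the 5 highest and 5 lowest differences between lines, up to 4 members of each list with the largest mean ratio, and up to 4 genes per line and direction measured in 1 condition only. The last part was a label check with CCND1, MAF, CCND2, ITGB7, SDC1 and CD38. Other genes named are said to be chosen after their values were seen. Names that are only clone or probe identifiers were counted and not named. Some genes that the rule names are not reported here. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except where the text says otherwise.

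The limma step was tested on simulated arrays built on the 16560 genes of the comparison over both lines, with noise of 0.10 (SD, log2) and no dye bias of single probes. It recovered 99% of 100 genes changed 1.5-fold and all of 100 genes changed 2-fold (100%). The fitted median was 0.40 on the log2 scale for the 1.5-fold genes and 0.77 for the 2-fold genes. There were 27 false calls, and 5 calls where nothing was changed. The 27 were a larger share of the calls than the adjusted threshold aims at. The simulated noise had a single SD, so the recovery does not check the intensity trend. The count on the real arrays depends on that trend, with 813 genes past the threshold and 0 without the trend. A simulated list of 20 genes moved by 0.2 went from percentile 14.3 to percentile 100.

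The alternatives were no background correction, plain subtraction, a normexp offset of 16, median centring in place of loess, the software's own ratios, the value table, other filters on dim probes, the mean over all probes of a gene, other limma settings and other thresholds. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.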

Results

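Dual-colour arrays compared myeloma cells cultured with hyaluronan under shear stress, which the labels call spheroids, with cells of the same line cultured with hyaluronan but without shear, after 24 hours. KMS12 and MM.1S were profiled once each, which gave 4 groups of 1 sample on 2 arrays. The median raw signal was 40.8 (KMS12) and 41.3 (MM.1S) in the static channel and 84.8 and 83.6 in the shear channel, over median backgrounds of 25 and 25, and of 68 and 67. In KMS12, 18600 genes were well above background in both conditions, and 13308 of these had a gene symbol. In MM.1S there were 18445 such genes, 13435 of them with a symbol. The static and shear channels of an array correlated at r = 0.998 (KMS12) and 0.999 (MM.1S) across genes, against 0.931 between the static cultures of the lines. The ratios were small. Their SD over genes was 0.15 in KMS12 and 0.13 in MM.1S on the log2 scale.

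The first comparison asked which genes differed between KMS12 cells under shear and KMS12 cells without shear. Some metallothionein genes, which encode metal-binding proteins, were among the lowest under shear. MT2A (chromosome 16, 56643332 to 56643391, hg19) had a log2 ratio of -0.89, MT1L of -0.77, MT1E of -0.60 and MT1M of -0.60. Some non-coding RNA genes were also among the lowest. RNU4ATAC, an RNA of the minor spliceosome, was at -0.90 (other probe -0.20), SCARNA22 at -0.54 and the ribosomal RNA gene RNA5-8SN5 at -0.52. The chemokine gene CCL3 was at -0.53. Metallothionein probes share sequence, and their ratios are not independent of each other. At the upper end, CC2D1A (1.05), ZNF865 (1.03), SLC66A1 (0.95) and EXOSC2 (0.81) were read by very bright probes with mean log2 intensities of 17.7, 17.7, 17.5 and 17.3, whose cross-hybridisation could not be examined. Of the 3 probes of CC2D1A, the lowest gave -0.08, and the lowest of the 3 for EXOSC2 gave 0.02. The other probes of ZNF865 gave 0.06 and 0.06. PTPRC, which encodes the leukocyte surface phosphatase CD45, was at 0.91, but its other probe gave 0.12. LANCL3 (0.88), TRIM44 (0.83) and ARHGEF15 (0.82) completed the upper end, and the other probe of TRIM44 gave 0.04. In all, 2 genes were 2-fold apart, both higher under shear (CC2D1A and ZNF865). A 1.5-fold threshold gave 115 genes, 110 higher and 5 lower, against 749 (553 and 196) with the software's own ratios, 265 (262 and 3) with median centring and 64 (60 and 4) with the mean over all probes of a gene. With no replicate culture, none of these ratios has a test. The count of 2 became 69 with the software's own ratios, 21 with median centring, and 0 with the mean over all probes of a gene.

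The next comparison asked the same of MM.1S. EGR1, an immediate early transcription factor gene (chromosome 5, 137804891 to 137804950), had the lowest ratio, -1.59, and FOS, another immediate early gene, was at -0.78. In KMS12 both genes were well above background only in the static culture, with bounds of 1.44-fold (EGR1) and 1.26-fold (FOS) over the shear culture. These bounds leave out the software's error, which was 0.37 for EGR1 and 0.47 for FOS on the log2 scale. The static channel, with its lower background, alone detected 2491 genes in KMS12, against 223 detected only under shear. Next in MM.1S came LRRC2 (-0.65), CASC15 (-0.63), CCNT2-AS1 (-0.63), NALF1-IT1 (-0.63), LINC02245 (-0.56) and LINC02682 (-0.55), of which all but LRRC2 are non-coding RNAs. The chemokine gene CCL4L2 had the highest ratio, 1.21. Its probe may also read near-identical CCL4 copies. LANCL3 (0.70), the immunoglobulin-like gene IGLL5 (0.65), LINC01793 (0.62), CCDC9 (0.61) and the interleukin receptor gene IL18RAP (0.61) followed. IGLL5 lies in a family of near-identical sequences. CC2D1A (0.59) and ZNF143-AS1 (0.59) completed the upper end, and the other probes of CC2D1A gave -0.11 and -0.08. In all, 2 genes were 2-fold apart, CCL4L2 higher and EGR1 lower under shear. The 1.5-fold threshold gave 22 genes, 13 higher and 9 lower, against 582 (400 and 182) with the software's own ratios, 200 (198 and 2) with median centring and 12 (9 and 3) with the mean over all probes of a gene. None of these ratios has a test. The count of 2 became 52 with the software's own ratios, 5 with median centring, 1 with the mean over all probes of a gene and 0 among genes above the median intensity.

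**Figure D1:**
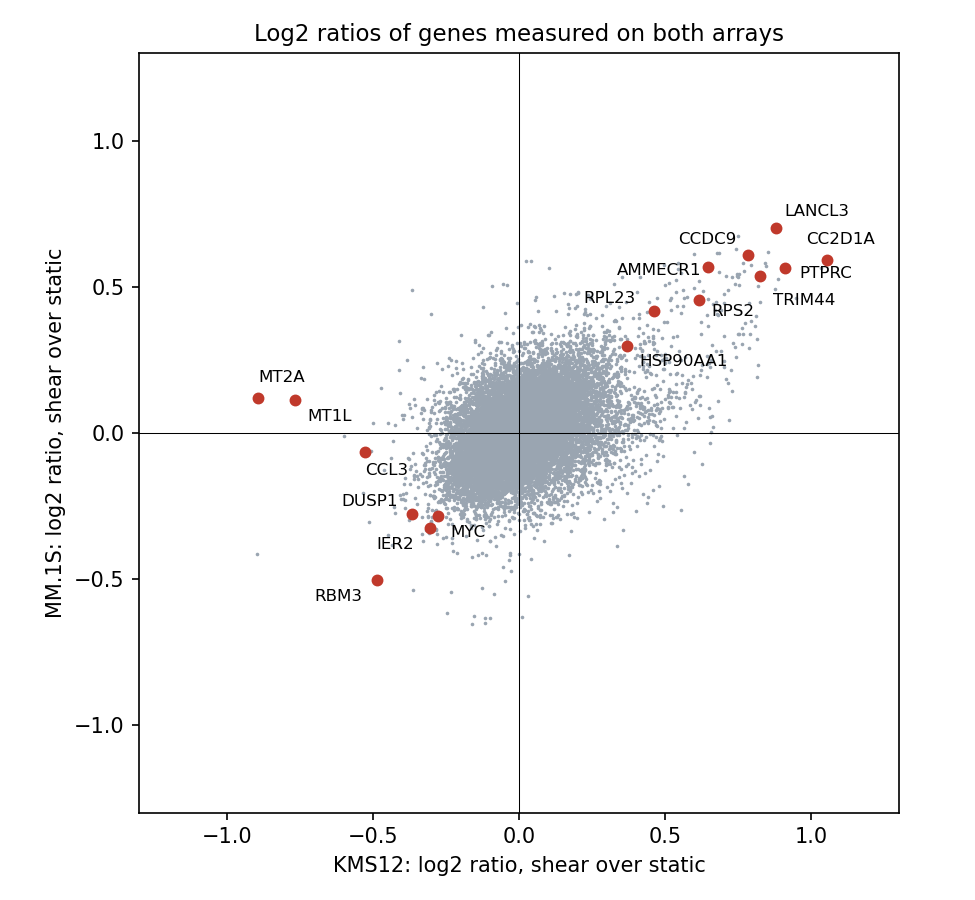
Each grey point is 1 of the 16560 genes measured on both arrays, with its log2 ratio of shear over static in KMS12 (x axis) and in MM.1S (y axis), and red points carry gene names. RBM3 lies near -0.5 on both axes, while MT2A lies at -0.89 in KMS12 and at 0.12 in MM.1S.

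The ratios of the lines were then set against each other to find genes that differed the same way in both. RBM3, which encodes a cold-inducible RNA-binding protein, was lower under shear in KMS12 (-0.49) and in MM.1S (-0.50). Its mean ratio was -0.50 ± 0.04 (SE, limma adjusted p = 0.000697, lower in both lines, n = 2 lines), at chromosome X, 48436055 to 48436114. Its other probe gave -0.29 and -0.35. RNU4ATAC (mean -0.66, limma adjusted p = 0.0069, with its other probe at -0.20 and -0.21), RNA5-8SN5 (-0.41, 0.0046) and the small nucleolar RNA SNORA2C (-0.41, 0.0053) were also lower in both lines. So were MAP6D1 (-0.40, 0.0067), TM9SF4 (-0.34, 0.0058), the immediate early gene IER2 (-0.31, 0.0044), LINC01564 (-0.35, 0.028), PIGL (-0.33, 0.026) and SNORD37 (-0.33, 0.036). For PIGL the other probe gave 0.01 in KMS12.

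The genes highest in both lines were LANCL3 (mean 0.79, limma adjusted p = 0.000554), CCDC9 (0.70), LINC01793 (0.65), IL18RAP (0.61), AMMECR1 (0.61), LINC01122 (0.68), PLAAT5 (0.66), PTPRC (0.74), CC2D1A (0.82) and ZNF865 (0.80), with limma adjusted p-values of at most 0.00463. LANCL3, CCDC9, LINC01793 and IL18RAP had 1 probe above background in all channels. The weaker probe of AMMECR1 gave 0.11 in KMS12 and 0.19 in MM.1S, that of PLAAT5 gave 0.32 and 0.06, and that of LINC01122 gave 0.08 and -0.13. The weaker probe of PTPRC gave 0.12 in KMS12 and 0.02 in MM.1S. In KMS12, the other probes of CC2D1A gave 0.13 and -0.08, and those of ZNF865 gave 0.06 and 0.06. In MM.1S, these probes gave -0.11 and -0.08 for CC2D1A, and 0.11 and 0.11 for ZNF865. In all, 813 of 16560 genes passed limma's threshold over both lines, 533 higher and 280 lower under shear, with a median absolute log2 ratio of 0.25. Only 39 of them reached 1.5-fold. No gene was 2-fold apart the same way in both lines, and 9 were 1.5-fold apart, all of them higher. These counts are open to dye bias, and the limma count was 0 at the same threshold without the intensity trend (3089 genes at an unadjusted p under 0.05) and 346 with the mean over all probes of a gene.

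Across these 16560 genes the ratios of the lines correlated at r = 0.45 (Pearson) and rho = 0.42 (Spearman). Genes are not independent replicates, and this was the 1 relation between lines planned. Probes of the same gene were then compared, in part after the results were seen. For 3432 genes with at least 2 probes at separate positions, the brightest probe correlated with itself between lines at r = 0.58, and the next probe with itself at r = 0.31. Different probes of one gene correlated between lines at r = 0.03 and 0.06. Of the 230 genes past the limma threshold that had such a further probe, that probe had the same sign in 137 (59.6%), and its median ratio was 0.04 for the higher genes and -0.02 for the lower ones. In 40 of them, the further probe lay beyond 0.1 in the same direction in both lines. Some further probes lay beyond 0.1 in the opposite direction in both lines, among them those of BTBD7 (-0.18 and -0.26) and SH3GLB1 (-0.24 and -0.21).

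Genes of the fixed lists were then compared. Ribosomal protein genes had a list median of 0.16 in KMS12 (percentile 100 of random lists) and 0.16 in MM.1S (percentile 100). Of 32 members tested, 10 were higher by limma and 22 did not pass, or 25 and 7 when adjusted over the list alone. RPS2 (mean 0.54, limma adjusted p = 0.0029), RPL23 (0.44, 0.0036) and RPS15 (0.31) were among the highest of the list, and the weaker probe of RPL23 gave 0.33 and 0.28. Of the 3 probes of RPS2, the lowest gave -0.00 in KMS12 and 0.03 in MM.1S. Of the 32, 28 had mean log2 intensities above 16, and the list median was 0.01 in KMS12 and 0.02 in MM.1S with the software's own ratios. Of the 18600 genes measured in KMS12, 18415 were left without genes above 16. The brightest bin of the matching therefore also held dimmer genes, and the percentiles of this list are not closely matched on intensity.

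Heat shock genes, which encode protein-folding chaperones, had medians of 0.12 in KMS12 (percentile 99.0) and 0.16 in MM.1S (percentile 100). Of 14 members tested, 5 were higher by limma and 9 did not pass, or 9 and 5 when adjusted over the list alone. HSP90AA1 had a mean ratio of 0.33 (limma adjusted p = 0.0071), HSPE1 of 0.31 (0.0096), HSPH1 of 0.29 (0.0058) and HSPD1 of 0.26 (0.019). The probes of HSP90AA1 disagreed, with the lowest at -0.08 in KMS12 and -0.05 in MM.1S. An overlapping probe of HSPE1 gave 0.21 and 0.22, and the other probe of HSPH1 gave 0.12 and 0.01. HSP90AA1, HSPE1 and HSPD1 were read by bright probes with mean log2 intensities of 16.2, 16.5 and 16.5. At the lowest under the alternatives, HSP90AA1 was at 0.12 in KMS12 and 0.07 in MM.1S, HSPE1 at 0.15 and 0.16, and HSPD1 at 0.08 and 0.09. The list median was then lowest at 0.10 in KMS12 and 0.09 in MM.1S.

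Immediate early and shear-responsive genes had medians of -0.06 in KMS12 (percentile 0.79) and -0.09 in MM.1S (percentile 0.11). Of 21 members tested, 4 were lower by limma and 17 did not pass, or 6 lower, 1 higher and 14 not passing when adjusted over the list alone. DUSP1, which encodes a phosphatase of MAP kinases, had a mean ratio of -0.32 (limma adjusted p = 0.031), IER2 of -0.31 (0.0044), MYC of -0.28 (0.0069) and KLF6 of -0.20 (0.036).

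ER chaperone and unfolded protein response genes had a median of -0.11 in KMS12 (percentile 0.02) and of 0.01 in MM.1S (percentile 48.7), where the sign changed with the processing. Of 21 members tested, 5 were lower by limma and 16 did not pass, or 7 lower, 3 higher and 11 not passing when adjusted over the list alone. SEC24D, a component of vesicle coats leaving the ER, had a mean ratio of -0.32 (limma adjusted p = 0.019) and the chaperone gene DNAJB11 of -0.22 (0.018). CALR (0.23, adjusted p = 0.052 by limma) and DNAJB9 (0.21, 0.089) did not pass. XBP1, the transcription factor gene of plasma cells, was at -0.18 (limma adjusted p = 0.047), and its sign in MM.1S turned under median centring.

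Other lists stood apart in a single line. ATF4 and amino acid stress genes had a median of -0.12 in KMS12 (percentile 0) and 0.05 in MM.1S (percentile 94.2). Of 20 tested, 1 was lower by limma (TRIB3, -0.18, adjusted p = 0.037) and 19 did not pass, against 2 lower when adjusted over the list alone. Cholesterol synthesis genes had a median of -0.01 in KMS12 (percentile 28.9), of either sign across the alternatives, and 0.12 in MM.1S (percentile 100). By limma 0 of 25 passed over all genes (7 at an unadjusted p under 0.05), and 4 were higher and 1 lower when adjusted over the list alone, with FADS1 (0.18) and SCD (0.17) among those largest in mean. Interferon response genes had a median of 0.04 over 14 genes in KMS12 (percentile 82.0) and -0.11 over 21 genes in MM.1S (percentile 0.01). These medians rest on different sets of genes. By limma 0 of 14 passed over all genes (4 at an unadjusted p under 0.05), against 1 lower when adjusted over the list alone. BST2 was at -0.04 in KMS12, of either sign across the alternatives, and -0.25 in MM.1S, and IRF7 was at -0.15 and -0.18. NF-kB targets had a median of 0.07 over 16 genes in KMS12 (percentile 96.0) and -0.06 over 17 genes in MM.1S (percentile 2.02). The MM.1S median was positive without a filter on dim probes, and the medians of both lines rest on partly different genes. Of 13 tested, 1 was higher by limma (NFKBIA, 0.16, adjusted p = 0.047) and 12 did not pass, or 2 higher and 2 lower when adjusted over the list alone. DNA replication genes had a median of -0.06 in KMS12 (percentile 1.45), positive under median centring, and 0.01 in MM.1S (percentile 69.8). Of 24 tested, TYMS (0.16) was higher and CDC45 (-0.16) lower by limma, against 1 higher and 3 lower when adjusted over the list alone.

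**Figure D2:**
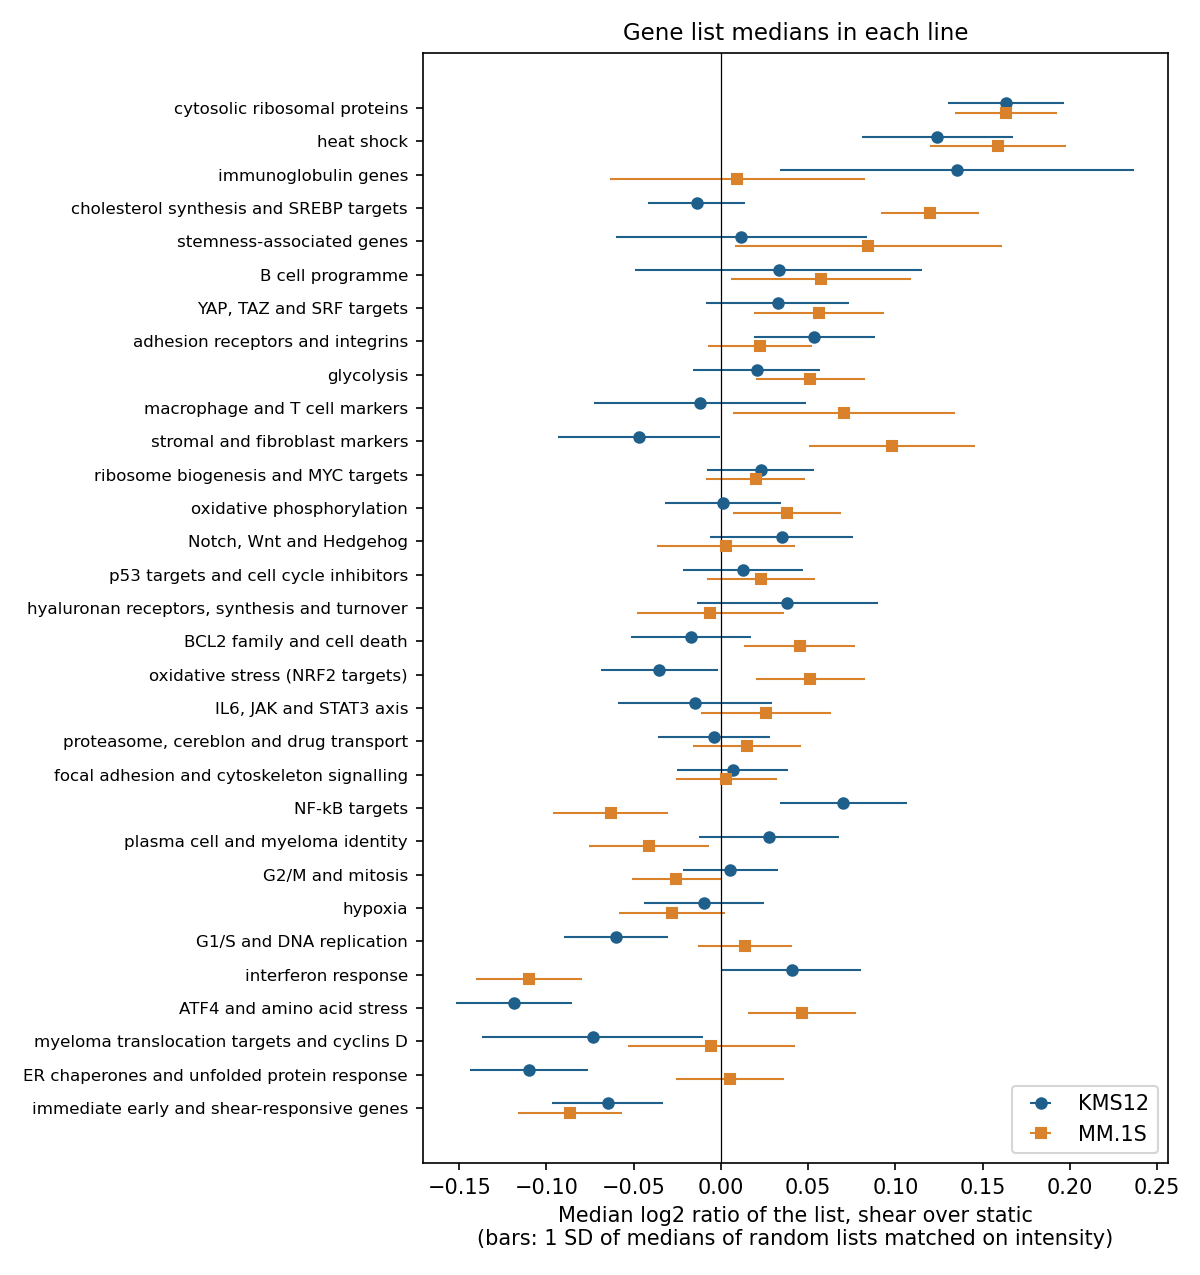
Median log2 ratio of shear over static (x axis) of each of the 31 gene lists (y axis) in KMS12 (circles) and MM.1S (squares). Bars show 1 SD of the medians of random lists matched on intensity, and the ribosomal protein and heat shock lists lie highest by the mean of both lines.

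The remaining 22 lists had percentiles between 6.33 and 97.1 in both lines. Of their 309 member tests, 7 were higher and 7 lower by limma over all genes, and 20 higher and 11 lower when adjusted over the list alone. Among hyaluronan-related genes, by limma 0 of 8 passed over all genes (1 at an unadjusted p under 0.05) and 1 was higher when adjusted over the list alone (HMMR, a hyaluronan receptor, mean 0.15, limma adjusted p = 0.064 over all genes). The hyaluronan receptor gene CD44, named after its values were seen, was at -0.06 in KMS12 and 0.01 in MM.1S, of either sign in both lines across the alternatives. Of 16 adhesion receptors tested, CD58 (0.27, limma adjusted p = 0.034) was higher and ICAM2 (-0.19, 0.041) lower, against 3 higher and 1 lower when adjusted over the list alone. Among 14 plasma cell genes, 1 was lower (XBP1). Of 20 focal adhesion genes, PTK2B (0.36, limma adjusted p = 0.031) was higher, and its weaker probe gave 0.25 and 0.11. PRDX1, an antioxidant enzyme gene, was at 0.35 (limma adjusted p = 0.0046), but its other probe gave -0.22 and -0.16. Of the mitotic genes, CDK1 (-0.22, limma adjusted p = 0.022) and KIF11 (-0.21, 0.021) were lower and CENPF (0.18, 0.033) was higher, with the other CENPF probe at -0.02 and -0.10. Of the 19 hypoxia genes, 20 glycolysis genes and 25 oxidative phosphorylation genes tested, 0 passed by limma either way, and 1, 4 and 10 had an unadjusted p under 0.05.

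The difference between the ratios of the lines was then taken for each gene. MT2A had the largest difference, -1.01 (KMS12 minus MM.1S), since its ratio was -0.89 in KMS12 and 0.12 in MM.1S, and MT1L followed with -0.88. Of 9 metallothionein genes measured in both lines, 8 were below 0 in KMS12 and 4 in MM.1S, with medians of -0.35 and 0.02, the latter of either sign across the alternatives. In KMS12, 7 lay more than 2 SD of repeated spots below 0, and MT1A was near 0 (-0.008). The lowest in MM.1S was MT1F at -0.07. The near-identical small RNAs SNAR-A3 (-0.85) and SNAR-B2 (-0.72) and the small nucleolar RNA SNORA70E (-0.71) were also lower in KMS12 relative to MM.1S. In the other direction stood P2RX2 (0.74), KCNQ5-IT1 (0.72), FAM230B (0.71) and LINC00504 (0.68). Of 16560 genes, 0 differed 4-fold and 39 differed 1.5-fold, a limit added after the data were seen. These differences had no replicate and were not tested. Their SD over genes was 0.15, and over the 10 spike-in controls it was 0.05.

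**Figure D3:**
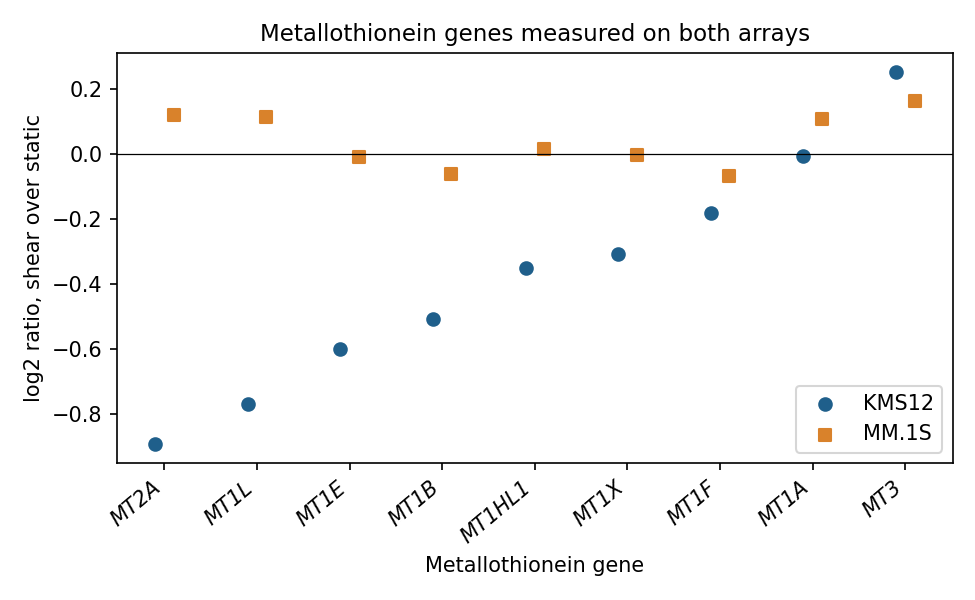
Log2 ratio of shear over static (y axis) of the 9 metallothionein genes measured on both arrays (x axis) in KMS12 (circles) and MM.1S (squares). In KMS12, 8 of the 9 lie below 0, with MT1A near 0, against 4 in MM.1S.

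The lines were also compared with each other within each condition, first as a check of the labels. MAF was 52.1-fold higher in MM.1S than in KMS12 in the static cultures and 58.6-fold higher under shear. ITGB7, an integrin gene regulated by MAF, was 35.5-fold and 47.4-fold higher in MM.1S, and CCND2 at least 136-fold and 155-fold higher. CCND1 was 8.39-fold and 8.55-fold higher in KMS12. MM.1S had more SDC1 (11.4-fold and 11.9-fold) and SLAMF7 (10.7-fold and 10.3-fold), both surface markers of plasma cells. The chemokine gene CCL3 was 26.3-fold and 42.4-fold higher in MM.1S. CD27, a receptor of the TNF family, was 45.3-fold higher in KMS12 in the static cultures and at least 61.2-fold higher under shear. SLAMF7, CCL3 and CD27 were chosen for this comparison after their values were seen. In total, 1047 of 20485 genes were at least 4-fold apart in both conditions, 510 higher in KMS12 and 537 higher in MM.1S. With 1 culture per line and condition these levels have no test, and the count was 2925 with the software's processed signals.

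Some genes were well above background in 1 condition only. The static channel, which had the lower background, alone detected 2491 genes in KMS12 and 2437 in MM.1S, against 223 and 230 detected only under shear. The largest bounds among named genes were MMP12, which encodes a macrophage elastase and was at least 1.74-fold higher under shear in MM.1S, and LHX5-AS1, at least 1.499-fold higher under shear in KMS12 and 1.35-fold in MM.1S. LINC00396 was at least 1.34-fold higher under shear in both lines. The software's error of its log2 ratio, which the bound leaves out, was 0.69 in KMS12 and 0.51 in MM.1S. PLA2G4F was at least 1.42-fold higher under shear in MM.1S, and its log2 ratio was 0.43 in KMS12, where both channels read it. In MM.1S, DTX3 was at least 1.34-fold higher in the static culture than under shear. In KMS12, where both channels read DTX3, its log2 ratio was 0.01, of either sign across the alternatives.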

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

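The limits used for this part and the tests on metallothionein genes were chosen after the results were seen. None of the differences between lines below was tested, since each line had 1 culture pair.

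Of 159 named genes measured in both lines, 16 had ratios of opposite sign, and 9 of these lay beyond 0.10 (2 SD of repeated spots) in both. The naming rule took the largest differences between lines, and these 9 are among them, so their presence here follows from the rule. Another part of the rule required the same sign, so 16 of 159 does not describe all genes. Over all 16560 genes measured on both arrays, 65.6% had the same sign in both lines. MT2A (-1.01, KMS12 minus MM.1S), MT1L (-0.88), SNAR-A3 (-0.85), SNAR-B2 (-0.72) and SNORA70E (-0.71) were lower under shear in KMS12 and higher in MM.1S. P2RX2 (0.74), KCNQ5-IT1 (0.72), FAM230B (0.71) and LINC00504 (0.68) were higher under shear in KMS12 and lower in MM.1S. LINC00504 was the one of these with a further probe above background in all channels, which gave 0.50 in KMS12 and -0.25 in MM.1S. The medians of 2 lists were also opposite and near the ends of the random lists. ATF4 and amino acid stress genes differed by -0.17, and NF-kB targets by 0.13, the latter with a sign in MM.1S that turned without a filter on dim probes. The NF-kB medians rest on 16 genes in KMS12 and 17 in MM.1S, with 13 measured in both, so part of their difference may come from the genes measured.

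Of 9 metallothionein genes, 8 lay below 0 in KMS12 (7 by more than 2 SD of repeated spots) and 4 in MM.1S. A dye bias of the probes cancels in the difference between lines only if it is equal on both arrays. The median difference was -0.36, against 0.10 for 2 SD of the spike-in differences. Separate probes of 179 of 3360 genes lay at least as far apart in this difference (at most 0.94). These are gaps within single genes, which do not show how far a median over 9 genes would move. The comparison therefore decides nothing, and dye bias stays open. The median difference stayed between -0.34 and -0.43 under the other background settings, median centring, the software's ratios, the value table and the mean over all probes. MT1A (-0.00814 in KMS12, positive under median centring) and MT3 (0.25) lay above MT2A by more than the software's errors, which argues against MT2A transcripts as the main signal of these 2 probes. Whether the other 7 of the 9 probes read separate genes stays open, since the family shares sequence. A difference between single cultures cannot be told apart from one between lines, with 1 culture pair per line. A difference between the lines in their response stays open and was not tested.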

How the results depend on the processing

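The run without genes above a mean log2 intensity of 16 was chosen after the results were seen. Each array pairs the samples of its line, so the limma test over both lines is already a paired one. Leaving out a line leaves no residual degrees of freedom, so no test was run without one. Except as given, the cause was not tested. Genes 2-fold apart numbered 2 in KMS12, but 21 with median centring, 69 with the software's ratios or the value table, 115 at 1.5-fold, and 0 with the mean over all probes or without the bright genes, which include both called genes. For MM.1S the 2 became 5 with median centring, 52 with the software's ratios or the value table, 22 at 1.5-fold, 1 with the mean over all probes and 0 above the median intensity, which leaves out both called genes. In both lines together the count of 0 became 2 with median centring, 3 with the software's ratios or the value table, and 9 at 1.5-fold. Responses that differ 4-fold numbered 0, or 1 with the software's ratios or the value table. The limma count of 813 ranged from 551 to 1218 under the settings that moved it by less than 1.5 times. It was 346 with the mean over all probes (342 of these among the 813), 0 without the intensity trend (3089 at an unadjusted p under 0.05), 1683 at an adjusted p of 0.1, and 6290 with median centring. That centring left the medians of detected genes at 0.12 in KMS12 and 0.16 in MM.1S, and 99.3% of its calls were higher, against 65.6% with loess. Aquantile scaling moves no ratio, so its 813 says nothing. The correlation between lines of 0.45 was 0.30 with the software's ratios or the value table, 0.29 without a filter, and 0.59 above the median intensity. Line differences of 1047 genes became 2925 with the software's processed signals. Of 682 values of list medians under the alternatives, 591 stayed within the spread of random lists. The sign was opposite to the reported one in 83 of the 682, and 35 of the 62 medians had either sign. Among medians in the outer 2.5% of random lists at either end, 2 values turned sign, DNA replication in KMS12 (0.0332 with median centring) and NF-kB targets in MM.1S (0.0310 without a filter). Of 2303 values of named genes, 2178 stayed within the software's error. The sign was opposite in 65, and 44 of the 329 ratios had either sign. Among genes past the limma threshold or 2-fold apart, 3 values turned sign, NPM1 (-0.0429) and PSMC2 (0.10) in KMS12 with the mean over all probes, and XBP1 (0.10) in MM.1S with median centring. Signal over background limits the dim genes, as 43.2% to 48.4% of spots were well above it.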

Other observations

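The RNA classes, the genes of the next paragraph and the tests of dye bias as most of the cause and of the other RBM3 probe alone were chosen after the results were seen. Small nuclear RNA genes, counted with the near-identical SNAR family as the reference annotates them, had a median ratio of -0.32 in KMS12 and 0.10 in MM.1S over 16 genes, with 14 below 0 in KMS12 and 6 in MM.1S. The ratios of the SNAR genes are not independent of each other, so these counts do not stand for 16 separate RNAs. Small nucleolar RNA genes had medians of -0.04 and 0.03 over 195 genes. Long non-coding RNA genes had medians of 0.03 and 0.01 over 936 genes, of either sign in both lines across the alternatives. The RNA of the signal recognition particle RN7SL1 was at 0.29 in KMS12 and -0.30 in MM.1S.

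The genes below were picked by eye from the 40 past the limma threshold whose further probe lay beyond 0.1 in the same direction in both lines. The agreement between their probes therefore follows from that choice. Lower under shear were PDIA3, an ER disulfide isomerase (-0.17 in KMS12 and -0.22 in MM.1S, with the other probe at -0.24 and -0.23), FKBP11 (-0.19 and -0.26, other probe -0.17 and -0.28) and SELENOF (-0.26 and -0.18, other probe -0.16 and -0.17). Higher under shear were the ribosomal protein gene RPL13A (0.27 and 0.28, other probe 0.19 and 0.24), the chromatin-associated protein gene PTMA (0.50 and 0.22, other probe 0.55 and 0.21) and the non-coding RNA NEAT1 (0.34 and 0.36, other probe 0.34 and 0.16). The alternatives turned no sign here, but some ratios came near 0. RPL13A fell to 0.06 in KMS12 and 0.09 in MM.1S, PTMA to 0.27 and 0.05, and SELENOF came to -0.20 and -0.05.

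Ratios of shear over static were shared by both lines (r = 0.45). A linear effect of the probes' base counts is argued against as the whole cause, since r was 0.44 after a linear fit on these counts. That fit cannot speak to effects of composition that are not linear or that depend on base order. Different probes of one gene correlated at r = 0.11 in their mean ratio, above the highest of 1000 random pairings (0.05). That value also holds what is particular to each line, since the differences between lines correlated at 0.14, so it does not decide whether dye bias is the whole cause. Between lines, the pairings of different probes gave r = 0.0573 and 0.0254, on either side of the highest random pairing (0.0502), so that the whole cause stays open. The same probes gave 0.58 and 0.31 (geometric mean 0.42), and the gap is consistent with a dye bias of single probes as most of the cause, although transcript forms read by single probes stay open.

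RBM3 was lower under shear in both lines, and 5 of 14 heat shock genes were higher by limma over all genes, which raised the hypothesis of a warmer culture. CIRBP, another cold-induced gene, named here after the RBM3 value was seen, was at -0.21 in KMS12 and at 0.0862 in MM.1S. The bound set in advance was the SD of repeated spots (0.05), which leaves out the spread between cultures and is narrower than the software's error of 0.20, so this value decides nothing and a warmer culture stays open. Over the pattern, 10 further probes of 8 genes had a median in its direction of 0.07 in KMS12 and 0.0135 in MM.1S, as a dye bias of the heat shock probes would give. The further probes were also the dimmer ones of each gene, whose ratios the normexp offset draws more towards 0. These medians therefore do not single out dye bias. For RBM3 alone, a dye bias of a single probe as the whole cause is argued against, since its other probe gave -0.29 and -0.35. A dye effect shared by both RBM3 probes cannot be told apart from a change under shear, since the dyes were not swapped. A response of RBM3 to shear or clustering stays open and may be followed up with a dye swap.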
